A study of Homo sapiens with 6 samples.

How the data were processed

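The data are read counts per gene from 6 stranded mRNA sequencing libraries of SW1353, an established human chondrosarcoma cell line. The cells had been infected with lentiviral particles, either with an HMGA2 overexpression construct or with a negative control, and each group holds 3 libraries, numbered 1 to 3 in the labels. RNA was extracted with TRIzol and libraries were made with an Illumina stranded mRNA kit, per the labels' protocols.

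The table deposited by the authors gives whole-number counts for 20036 genes by Ensembl identifier and symbol, with 1 column per library, not scaled for depth or transcript length. The submitters' processing notes name FastQC 0.12.0, Salmon 1.3.0, R 4.0.2, DESeq2 1.28.1 and the build GRCh38, per the submitters' processing notes without a role for any of them. The annotation release, the strand setting, how reads shared between near-identical genes were divided, and whether estimated counts were rounded are not given in the sources used here. Of the 20036 genes, 629 carried no symbol, 11 symbols occurred more than once, 2834 genes had a count of 0 in every library, and 19739 are protein-coding in GENCODE release 29. Genes outside that table, non-coding RNAs among them, were not analysed here.

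Total counts were 17551815, 18161355 and 17516632 in control replicates 1, 2 and 3 and 14079227, 14573606 and 18238226 in HMGA2 overexpression replicates 1, 2 and 3. The median count per gene was 62, 71 and 61 in the control libraries and 34, 34 and 44 in the HMGA2 overexpression libraries. A count of 0 allows up to 3 counts, which is 0.164 to 0.213 CPM per library, and this floor covers counting error only. Counts between replicates were compared by a chi-square statistic per degree of freedom over genes with at least 10 counts in the pair. It was 4.20 to 6.27 between control libraries and 35.2 to 63.4 between HMGA2 overexpression libraries, so no pair agreed within sampling noise and every library was counted as 1 replicate. The labels do not say whether the replicates are separate cultures or infections, so p-values measure only the spread between these samples, which may be technical.

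Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, two-sided, with group as the only term. It fits 1 dispersion per gene over both groups, so the wider spread between HMGA2 overexpression libraries is not modelled separately. Low counts were removed with edgeR's default expression filter, library sizes were scaled by TMM (trimmed mean of M-values), and p-values were adjusted by the Benjamini-Hochberg method over the 12772 genes tested, with a threshold of 0.05. TMM factors were 1.13, 1.19 and 1.13 for the control libraries and 0.880, 0.885 and 0.843 for the HMGA2 overexpression libraries. Log2 fold changes are HMGA2 overexpression over control, and their standard error (SE) is the size of the fold change divided by the square root of the F statistic. CPM values are counts divided by the TMM-scaled library size, with SD over 3 libraries. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 46 of 47 lists with at least 5 tested members. camera compares a list with all other tested genes, and HMGA2 is in no list.

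The groups, the tests, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The rule took HMGA2, then the 12 largest rises, HMGA2 among them, and the 12 largest falls. These had to pass the threshold and have a mean of at least 5 CPM in the higher group and a gene symbol. The rule also asked for all 3 libraries of a group to lie above all 3 of the other. From each list that passed camera it took up to 4 members in the direction of the list and up to 2 against it. From each other list with at least 3 members past the threshold it took the 3 with the smallest adjusted p. This gave 151 genes. Of these, 2 are not reported here by name. Genes named outside this rule are said to be so.

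The alternative settings fixed in advance were RLE size factors, upper-quartile factors, library totals alone, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, a minimum fold change of 1.2 (glmTreat), HMGA2 left out, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and the fry test. A correction for transcript GC content and length was chosen after the data had been seen. It fits natural splines (5 degrees of freedom each) of GC content and log2 length of the longest protein-coding transcript in GENCODE release 29 to each library's log2 CPM, relative to the mean of all libraries, and enters as an offset. It could be run for 12743 genes, 99.8% of those tested. It was also run for GC content alone, for length alone, with the block, and without HMGA2 overexpression replicate 2.

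The procedure was tested on simulated data for this comparison of 3 against 3 libraries. Without a GC and length trend, on 12555 genes, the uncorrected test recovered 71.9% of genes changed 2-fold and 16.5% of those changed 1.5-fold, and 4.49% of its calls were unchanged genes. With a trend of the observed size added, on 12411 genes, the uncorrected test called 5111 unchanged genes and the corrected one 7. The corrected test recovered 70.5% of the 2-fold and 12.5% of the 1.5-fold changes. The added trend was built from the same splines that the correction fits, so its removal was fixed in advance. The simulation cannot show how the correction acts on a trend of another form or on a response that follows GC content. A simulated list of 40 genes raised 1.5-fold was called by camera, and 1 of 200 random lists had an unadjusted p under 0.05. Genes were simulated independently of each other, so this cannot show how often camera wrongly calls lists of correlated genes.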

Results

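Messenger RNA was measured by sequencing in SW1353 cells, a human chondrosarcoma line, to ask which genes change when HMGA2 is overexpressed from a lentivirus. HMGA2 is an architectural chromatin protein that binds AT-rich DNA. The series holds 3 HMGA2 overexpression libraries and 3 negative-control libraries, with 14079227 to 18238226 counts per library.

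HMGA2 was far higher in every library of the overexpression group. Its count was 799, 1089 and 818 in control replicates 1, 2 and 3 and 7389, 6582 and 10121 in HMGA2 overexpression replicates 1, 2 and 3. The mean rose from 44.0 ± 5.74 to 588 ± 74.5 CPM (SD, n = 3 each), a log2 fold change of 3.74 ± 0.17 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.21e-07). The gene (ENSG00000149948) lies on chromosome 12 from 65824131 to 65966295 in GRCh38, as annotated in GENCODE release 29. The counts do not separate the delivered from the endogenous transcript. Values with the GC and length correction use the annotated HMGA2 transcript (38.8% GC, 8094 nucleotides). The delivered insert is not described in the labels, so these features may not apply to it.

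**Figure D1:**
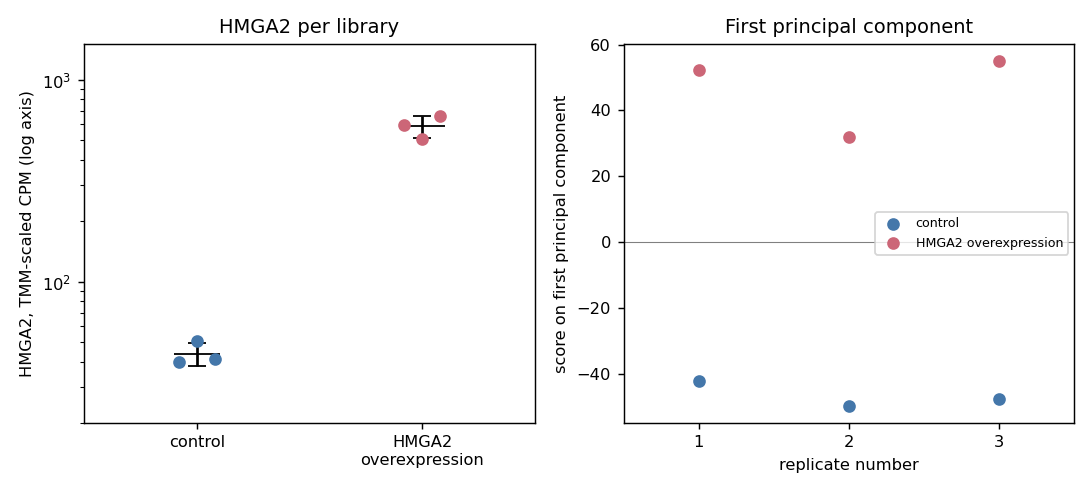
HMGA2 in TMM-scaled CPM per library on a log axis, with mean and SD (left), and the score of each library on the first principal component of log2 CPM against its replicate number (right). All 3 HMGA2 overexpression libraries lie above all 3 controls in both panels, and HMGA2 overexpression replicate 2 lies nearest to the controls on the component.

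Many other genes differed between the groups. Of 12772 genes tested, 3281 rose and 3196 fell, 1754 and 979 of them by 2-fold or more, and 6295 did not pass (edgeR quasi-likelihood test). The first principal component held 69.6% of the variance and separated the groups. Without HMGA2 overexpression replicate 2, which lay nearer the controls, 3483 genes rose and 3215 fell. The balance depended on scaling. Genes that rose made up 50.7% of calls with TMM, 56.4% with RLE factors, 38.6% with upper-quartile factors (2810 against 4464 genes) and 26.3% with library totals (2155 against 6033). The median log2 fold change of all tested genes was -0.14, -0.06, -0.31 and -0.54 in that order, and fold changes are given relative to the TMM scale.

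Fold changes followed the base composition and length of transcripts across genes. In the decile of genes with the lowest GC content (median 37.4%) the median log2 fold change was -0.39 and 1.57% of genes rose. In the decile with the highest (median 64.4%) it was 1.13 and 77.7% rose. The median was 0.64 in the decile with the shortest transcripts and -0.52 in the decile with the longest. Across genes, which are not independent replicates, Spearman's rho of fold change was 0.56 with GC content and -0.43 with length, and both together accounted for 47.1% of the variance of fold changes. With a correction for GC content and length, 2149 genes rose and 1587 fell. Of the uncorrected calls, 1646 rises and 1095 falls remained, 1580 rises and 2101 falls were lost, and 55 rises became falls, while without HMGA2 overexpression replicate 2 the corrected fit reversed 110 calls.

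**Figure D2:**
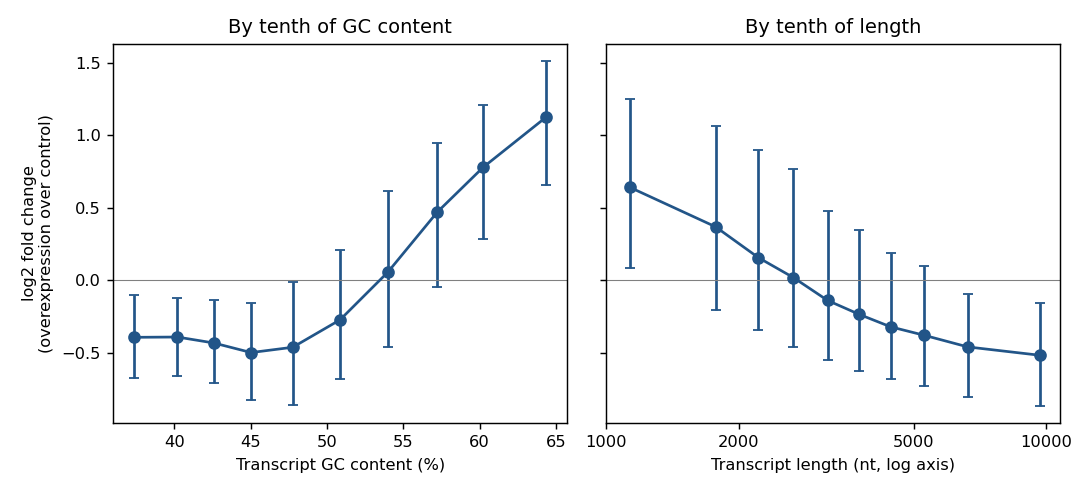
Median log2 fold change (points) and interquartile range (bars) of the tested genes in deciles of transcript GC content in percent (left) and of transcript length in nucleotides on a log axis (right). The median runs from -0.39 in the lowest decile of GC content to 1.13 in the highest, and from 0.64 for the shortest transcripts to -0.52 for the longest.

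After HMGA2, the largest rises by the naming rule were CBLN1, a secreted synapse organiser, at 3.35 ± 0.36 (log2, SE), IGFL1 at 3.31 ± 0.26, the protease gene CTSG at 3.28 ± 0.34, SYT12 at 3.15 ± 0.44 and LPL, lipoprotein lipase, at 2.97 ± 0.38. LPL rose from 0.695 ± 0.304 to 5.53 ± 1.84 CPM (SD, n = 3). PRX followed at 2.82, C11orf86 at 2.73, TPGS1 at 2.58, CCN5 at 2.54, the protease inhibitor gene SLPI at 2.48 and DUSP9, a MAP kinase phosphatase, also at 2.48. With the correction all 12 rises, that of HMGA2 included, were still called. LPL then stood at 3.49 and CBLN1 at 3.19, whereas C11orf86 moved to 1.53, TPGS1 to 0.90, CCN5 to 1.39 and DUSP9 to 1.44.

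The deepest fall by the naming rule was that of CXCL8, the neutrophil chemokine interleukin-8, at -3.81 ± 0.36. It went from 7.76 ± 1.38 to 0.561 ± 0.355 CPM (SD, n = 3). RELN, the matrix glycoprotein reelin, followed at -3.20 ± 0.34, F3, tissue factor, at -2.85 ± 0.23, the transketolase-like gene TKTL1 at -2.58 ± 0.24 and the Groucho-family corepressor TLE4 at -2.48 ± 0.24. MYH8 had -2.41, MGAM -2.27, TRANK1 -2.27, the orphan nuclear receptor gene NR2F1 -2.20, KSR2 -2.14, OLFML1 -2.01 and LGR5, an R-spondin receptor, -1.95. With the correction all 12 falls were called, CXCL8 at -3.72, F3 at -2.56 and NR2F1 at -2.64. By the rule, each of these genes separated all 3 libraries of a group from all 3 of the other, which chance gives in 1 of 10 genes.

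**Figure D3:**
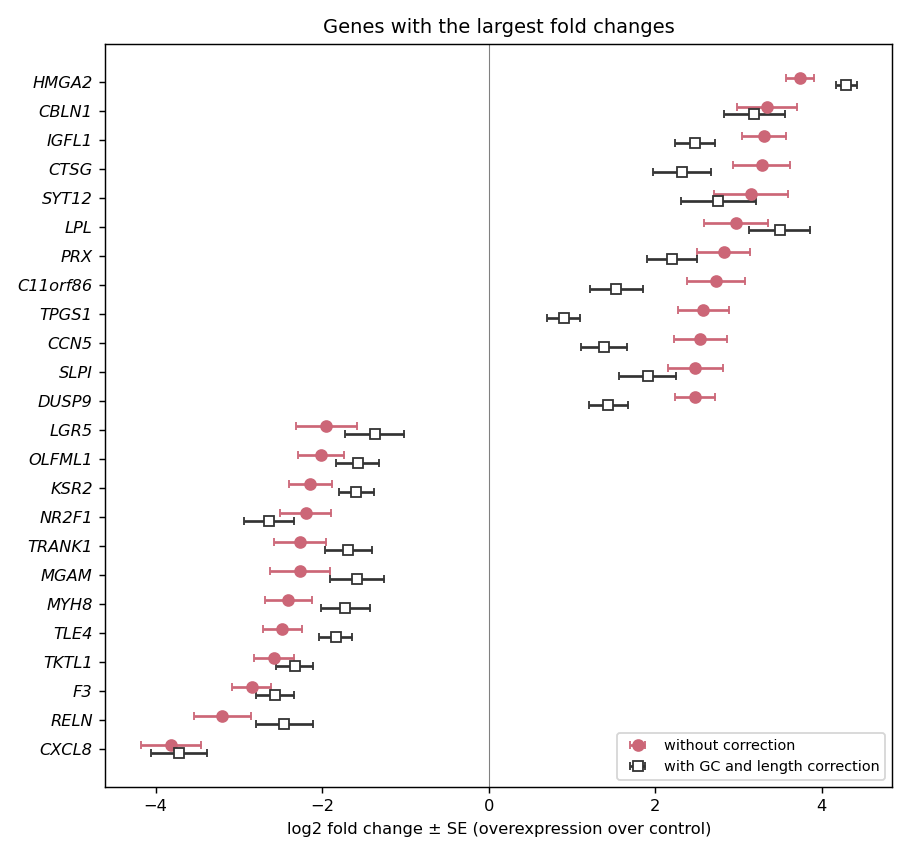
Log2 fold change with SE (HMGA2 overexpression over control, 3 libraries each) of HMGA2 and the other genes with the largest rises and falls by the naming rule, without correction (filled circles) and with the correction for GC content and length (open squares). Every gene keeps its direction, from HMGA2 at 3.74 and 4.30 with the correction to CXCL8 at -3.81 and -3.72.

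Gene groups were compared as 47 fixed lists. Each gene named from them is given with its log2 fold change, and counts in brackets are those with the correction. The SE over all 151 named genes was 0.13 to 0.44, and their adjusted p was at most 0.0200 (edgeR, Benjamini-Hochberg). Camera called 3 lists. Adjusted over the list alone, counts were unchanged in 35 lists and are given for the other 12. Leaving out 1 library changed which direction had more members in 6 to 12 of the 47 lists and moved a count by over 1.5 times in 7 to 22, and DESeq2 did so in 8 and 7. These counts, and those of other scalings that did either, are given with each list, rises before falls unless their sentence names falls first. The correction was repeated without HMGA2 overexpression replicate 2 but not without any other library, and its counts are given by the same rule.

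Ribosomal protein genes rose together. Of 49 tested, 33 rose and 1 fell, with a median of 0.58, and adjusted over the list alone 36 rose and 1 fell (camera, adjusted p = 1.34e-06; adjusted p = 0.845 with an estimated correlation). RPL35 rose by 1.86, RPS9 by 1.83 and RPLP0 by 1.29, while RPL22 fell by 0.43. With RLE factors 37 rose and 0 fell, with library totals 19 rose and 5 fell, and without HMGA2 overexpression replicate 2 the counts were 42 and 1. With the GC and length correction 22 rose and 5 fell, with a median of 0.20 (camera, adjusted p = 0.0257; adjusted p = 0.719 with an estimated correlation), and RPL22 was no longer called. Rises and falls were 37 and 0 with DESeq2, 29 and 0 without control replicate 1, and 26 and 0 without control replicate 2 or 3.

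Nuclear genes of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, also rose. Of 44 tested, 25 rose and 2 fell, with a median of 0.59, and adjusted over the list alone 26 rose and 3 fell (camera, adjusted p = 0.000398; adjusted p = 0.845 with an estimated correlation). CYC1 rose by 1.85, UQCRC1 by 1.57, NDUFV1 by 1.81 and COX8A by 1.75, and NDUFS1 (-0.85) and UQCRC2 (-0.57) fell. Counts were 21 and 5 with upper-quartile factors, 14 and 11 with library totals and 27 and 2 without HMGA2 overexpression replicate 2. With the correction 19 rose and 1 fell (camera, adjusted p = 0.000886; adjusted p = 0.455 with an estimated correlation), and COX8A, NDUFS1 and UQCRC2 were not called. Of the 13 mitochondrially encoded genes, 2 rose and 0 fell, or 1 and 0 adjusted over the list alone (edgeR; 2 and 0 at an unadjusted p under 0.05, 3 and 0 with DESeq2). With upper-quartile factors 1 rose and 1 fell, with library totals 0 rose and 7 fell, and with the correction 0 rose and 1 fell. For these 13 genes the counts were 4 and 0 without HMGA2 overexpression replicate 2, and 1 and 0 without any 1 of the controls or HMGA2 overexpression replicate 1. The corrected counts without HMGA2 overexpression replicate 2 were 21 rises and 2 falls, and 1 and 2 for the mitochondrially encoded genes.

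WNT pathway genes fell together. Of 27 tested, 16 fell and 3 rose, with a median of -0.82, and adjusted over the list alone 16 fell and 4 rose (camera, adjusted p = 0.0267; adjusted p = 0.845 with an estimated correlation). The receptor genes FZD7 (-1.19) and FZD8 (-1.57), the feedback gene AXIN2 (-1.75) and the secreted antagonist gene SFRP1 (-1.01) fell, and FZD2 (0.55) and WNT10B (0.78) rose. AXIN2 is both a target and an inhibitor of the pathway. With the correction 13 fell and 1 rose (camera, adjusted p = 8.52e-05; adjusted p = 0.455 with an estimated correlation), FZD8 stood at -2.35, WNT10B was not called, and FZD2 was called in the opposite direction at -0.54. The camera call was lost without control replicate 2 (adjusted p = 0.0711), without HMGA2 overexpression replicate 2 (adjusted p = 0.0552) and with the stricter low-count filter (adjusted p = 0.122). Counts were 1 rise and 14 falls without control replicate 1 and 0 and 19 with library totals.

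No other list passed camera without the correction, so the counts that follow describe members and not lists. They are to be read beside all tested genes, of which 3281 of 12772 rose and 3196 fell. With the correction 2149 of 12743 rose and 1587 fell. The hypertrophy, hedgehog, apoptosis, interferon and cholesterol lists lie near the uncorrected shares, so their uncorrected counts show nothing particular to them. Among matrix and adhesion genes, 14 of 33 fibrillar and interstitial matrix genes fell and 5 rose (15 and 2 with the correction). FN1, fibronectin, fell by 1.77 from 1159 ± 147 to 340 ± 94.7 CPM (SD, n = 3), and the collagen cross-linking gene LOX had -0.97 while its relative LOXL4 had 1.37. In the basement membrane list 7 of 21 fell and 1 rose (4 and 0), the laminin genes LAMC1 (-0.96) and LAMB1 (-0.72) falling and LAMB2 (0.74) rising, each without a call after the correction. For matrix proteases and inhibitors, 14 of 33 fell and 4 rose, or 15 and 4 adjusted over the list alone (11 and 1 with the correction). SERPINE2 (-1.29), TIMP2 (-1.17) and ADAMTS12 (-0.89) fell, the latter without a corrected call. Integrin and adhesion genes fell in 9 of 23 cases and rose in 1 (11 and 3), with CDH13 at -1.47 and ITGA6 at -1.11, while ITGB4 rose by 2.15. For fibrillar matrix the counts were 2 and 13 without control replicate 1 and 2 and 11 without control replicate 2 or 3. The basement membrane list had 1 and 4 without any 1 control and 2 and 6 without HMGA2 overexpression replicate 1. The protease list had 7 and 11 with DESeq2, 2 and 11 without control replicate 1 and 2 and 10 without control replicate 2. Upper-quartile factors gave 2 and 18 for fibrillar matrix and 1 and 17 for proteases, and library totals 1 and 23 for fibrillar matrix, 1 and 14 for basement membrane, 1 and 21 for proteases and 1 and 17 for integrins and adhesion. The basement membrane list had corrected counts of 0 and 7 without HMGA2 overexpression replicate 2.

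Mesenchymal transition genes included 8 of 20 that fell and 4 that rose (8 and 1 with the correction). ITGB1 (-0.83) fell as FN1 did, and the smooth muscle gene TAGLN rose by 1.45. Epithelial markers included 8 of 16 that rose and 3 that fell, or 9 and 3 adjusted over the list alone (3 and 0 with the correction). KRT18 (1.58), CLDN7 (1.96) and PKP3 (1.31) rose, PKP3 without a corrected call. In the actin and YAP list 8 of 25 rose and 5 fell, 6 and 9 with upper-quartile factors and 5 and 15 with library totals (4 and 3 with the correction). MYL9 (0.93, not called with the correction) rose as TAGLN did, and the YAP target CCN2 fell by 1.80. Epithelial markers had 6 rises and 1 fall without control replicate 2 or 3, and mesenchymal transition genes 2 and 12 with library totals. The actin list had corrected counts of 6 rises and 9 falls without HMGA2 overexpression replicate 2.

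Cartilage genes moved both ways. Of 13 tested, 5 rose and 3 fell, 3 and 4 with upper-quartile factors and 2 and 6 with library totals (3 and 3 with the correction). Without HMGA2 overexpression replicate 2, 3 rose and 5 fell, and without control replicate 1 or 3, 3 rose and 3 fell. The cartilage link protein gene HAPLN1 fell by 1.68, SOX9, a master regulator of chondrocytes, fell by 1.09 from 28.7 ± 1.81 to 13.5 ± 1.26 CPM (SD, n = 3), and COL9A2 rose by 1.58. Hypertrophy and osteogenic genes rose in 3 of 13 cases and fell in 3, 3 and 4 with upper-quartile factors and 3 and 7 with library totals (1 and 0 with the correction), with PHOSPHO1 at 0.97, PTH1R at 1.40 and ALPL at 1.06, all without a corrected call. The hypertrophy counts were 3 and 2 without control replicate 1, 3 and 1 without control replicate 2 or 3 or HMGA2 overexpression replicate 3, and 3 and 4 without HMGA2 overexpression replicate 2. HOX genes fell in 7 of 22 cases and rose in 2 (8 and 0 with the correction), HOXC6 at -1.22 and HOXD4 at 0.83, the latter without a corrected call. That balance depended on the fit, with 3 rises and 3 falls with DESeq2, 2 and 2 without control replicate 3, 1 and 3 without control replicate 2, 2 and 4 without HMGA2 overexpression replicate 1 and 3 and 4 without HMGA2 overexpression replicate 2. Upper-quartile factors gave 1 and 8 and library totals 0 and 10. Among adipogenic genes 6 of 16 rose and 3 fell, 6 and 5 with upper-quartile factors and 5 and 5 with library totals (2 and 1), with PLIN4 at 1.81 beside LPL, and CEBPB at 1.11 without a corrected call. Corrected counts without HMGA2 overexpression replicate 2 were 4 rises and 5 falls for cartilage, 1 and 2 for hypertrophy and 0 and 5 for HOX genes.

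Genes tied to HMGA2 biology moved both ways. In the HMGA family and IGF2BP list 1 of 12 rose and 3 fell (1 and 1 with the correction). IGF2BP2, a described HMGA2 target, fell by 0.88 from 62.0 ± 3.41 to 33.7 ± 2.38 CPM (SD, n = 3) and stood at -0.37 with the correction, still called. HMGA1 rose by 0.77 and IRS1 fell by 0.58, neither called with the correction. Of 28 let-7 target genes, 11 fell and 3 rose (5 and 2), with COL3A1 at -1.63 and CDC34 at 1.69, the latter without a corrected call. Stem cell factors fell in 5 of 14 cases with 0 rises by edgeR, or 4 and 0 adjusted over the list alone (3 and 1 with the correction). At an unadjusted p under 0.05 there were 2 rises, and with DESeq2 0. MYC fell by 1.03, and CD44 (-0.93) and LIN28A (-0.62) fell without a corrected call. The HMGA family list had 2 rises and 3 falls without control replicate 1, 1 and 1 without control replicate 2 or 3 and 2 and 2 without HMGA2 overexpression replicate 1. The let-7 list had 3 and 7 without control replicate 2 or 3, and stem cell factors 1 and 4 without control replicate 1 and 1 and 5 without HMGA2 overexpression replicate 1. The HMGA family list had 1 and 5 with upper-quartile factors and 1 and 8 with library totals, which gave 2 and 17 for let-7 targets. Stem cell factors had corrected counts of 0 and 4 without HMGA2 overexpression replicate 2.

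Signalling lists were mixed. In the TGF-beta list 8 of 25 fell and 2 rose (6 and 0 with the correction), CCN2 at -1.80, LTBP2 at -1.37 and INHBA at -1.06. For the BMP pathway 7 of 19 fell and 3 rose (4 and 3), with FSTL3 at 1.41, FST at -1.64 and BMPR2 at -0.94, the latter without a corrected call. Hedgehog genes fell in 4 of 13 cases and rose in 3, 3 and 3 with RLE factors and 6 and 2 with upper-quartile factors or library totals (3 and 1 with the correction), GLI3 at -1.04, FOXC1 at -1.26 and SMO at 0.92 without a corrected call. Of 16 NOTCH genes 6 rose and 4 fell, 3 and 5 with upper-quartile factors and 1 and 6 with library totals (3 and 3), with NOTCH2 at -1.11, HEY2 at 1.22 and HES4 at 1.63 without a corrected call. The FGF, EGF and MAPK list had 11 of 36 falls and 5 rises (10 and 2), with PHLDA1 at -1.15, ETV4 at 1.54 and JUNB at 1.32 without a corrected call. IGF and insulin genes fell in 8 of 22 cases and rose in 4 (3 and 4), AKT1 at 1.31, IGFBP3 at -0.98 and IGFBP6 at 1.07 without a corrected call. Among angiogenesis factors 9 of 23 fell and 6 rose (4 and 1), the receptor genes MET (-1.36) and NRP1 (-1.21) falling and EFNA1 (1.24) rising. Without HMGA2 overexpression replicate 1 there were 4 rises and 9 falls for TGF-beta, 6 and 6 for BMP, 3 and 3 for hedgehog and 5 and 5 for IGF genes. The BMP list had 1 and 5 without control replicate 1 or 3, 1 and 6 without control replicate 2 or HMGA2 overexpression replicate 3, and 1 and 7 without HMGA2 overexpression replicate 2. Hedgehog genes had 3 and 3 with DESeq2, 2 and 2 without control replicate 3, and 4 and 4 without HMGA2 overexpression replicate 2 or 3. NOTCH genes had 5 and 2 with DESeq2, 3 and 2 without control replicate 1 or 3, and 1 and 1 without control replicate 2. Without control replicate 2 or 3 the FGF list had 4 and 7 and the IGF list 4 and 5, and without HMGA2 overexpression replicate 3 the FGF list had 5 and 7. With library totals there were 1 rise and 18 falls for TGF-beta, 1 and 9 for BMP, 3 and 20 for FGF, 3 and 13 for IGF and 3 and 13 for angiogenesis factors. Without HMGA2 overexpression replicate 2 the corrected counts were 1 rise and 10 falls for TGF-beta, 2 and 3 for hedgehog, 2 and 3 for NOTCH and 2 and 7 for angiogenesis.

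Cell cycle and DNA repair lists were also mixed. In G1/S and replication 15 of 39 fell and 8 rose (8 and 10 with the correction), while E2F1 (1.79), TK1 (1.77) and MCM7 (1.21) had the smallest adjusted p and rose. In G2/M and mitosis 11 of 38 fell and 8 rose, 7 and 8 with RLE factors, 20 and 8 with upper-quartile factors and 24 and 7 with library totals (1 and 7), with MYBL2 at 1.18, CDC25B at 0.80 and AURKB at 0.82 without a corrected call. For DNA repair 10 of 36 fell and 6 rose, or 9 and 6 adjusted over the list alone (3 and 7 with the correction). XRCC3 (2.05) and OGG1 (1.15) rose and PRKDC, the catalytic subunit of DNA-dependent protein kinase, fell by 1.66. Of 28 p53 targets 10 rose and 7 fell, 10 and 10 adjusted over the list alone, 9 and 12 with upper-quartile factors and 9 and 13 with library totals (5 and 2 with the correction), with PHLDA3 at 1.88, BAX at 1.35 and FDXR at 1.91. Apoptosis regulators rose in 6 of 23 cases and fell in 6, 6 and 3 with RLE factors, 6 and 10 with upper-quartile factors and 5 and 12 with library totals (7 and 1), the pro-apoptotic genes BAX, BAK1 (1.39) and BBC3 (1.66) rising, BBC3 without a corrected call. CDK inhibitors and senescence genes fell in 5 of 17 cases and rose in 3 (3 and 2), with CXCL8 and IGFBP3 down and CDKN2A at 1.47 without a corrected call. The G2/M counts turned to 8 rises and 8 falls with DESeq2, 8 and 6, 8 and 4 and 8 and 7 without control replicates 1, 2 and 3, and 9 and 5 without HMGA2 overexpression replicate 1. For p53 targets they were 8 and 3 without control replicate 2 and 9 and 9 without HMGA2 overexpression replicate 1, and for CDK inhibitors 5 and 5 without HMGA2 overexpression replicate 3. Apoptosis regulators had 6 and 3 with DESeq2, 6 and 4, 6 and 3 and 6 and 5 without control replicates 1, 2 and 3, and 6 and 5, 6 and 4 and 7 and 4 without HMGA2 overexpression replicates 1, 2 and 3. Library totals gave 7 rises and 23 falls for G1/S and replication, 4 and 20 for DNA repair and 3 and 8 for CDK inhibitors. In the corrected fit without HMGA2 overexpression replicate 2 there were 7 rises and 4 falls for G2/M and 8 and 3 for p53 targets.

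Inflammatory and interferon genes split. In the NF-kB list 7 of 21 fell and 6 rose, 7 and 7 with RLE factors and 9 and 4 with library totals (7 and 4 with the correction), CXCL8 falling and RELB (2.33) and IL32 (1.31) rising. Type I interferon genes fell in 10 of 35 cases and rose in 8, 8 and 8 with RLE factors, 12 and 6 with upper-quartile factors and 15 and 5 with library totals (4 and 5), with ISG15 at 2.22, ISG20 at 1.51 and IFI35 at 1.11 without a corrected call. Of 19 antigen presentation genes 9 rose and 3 fell, 7 and 8 with library totals (9 and 5 with the correction), with the immunoproteasome genes PSMB10 at 1.80 and PSMB9 at 1.45 and HLA-DMA at 1.02. The NF-kB list had 7 rises and 7 falls with DESeq2, 6 and 6 without any 1 control or HMGA2 overexpression replicate 3, and 7 and 6 without HMGA2 overexpression replicate 1. Interferon genes had 8 and 8 with DESeq2, 7 and 5 and 7 and 4 without control replicates 1 and 2, and 8 and 7, 10 and 9 and 9 and 4 without HMGA2 overexpression replicates 1, 2 and 3. Antigen presentation had 9 and 1 without any 1 control.

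Metabolic and stress lists moved both ways. In hypoxia and glycolysis 13 of 36 rose and 6 fell, 10 and 11 with upper-quartile factors and 7 and 16 with library totals (13 and 3 with the correction). Here 14 rose and 10 fell without HMGA2 overexpression replicate 2, and without control replicate 2 or 3, 10 rose and 3 fell. The glycolytic genes PFKL (1.46), TPI1 (1.54) and ENO1 (1.01) rose. The integrated stress response and amino acid list had 13 of 27 rises and 2 falls (5 and 0), with the serine pathway genes PHGDH at 1.36 and SHMT2 at 1.56 and CEBPB without a corrected call. Among NRF2 and antioxidant genes 8 of 24 rose and 3 fell, 7 and 7 with upper-quartile factors and 6 and 11 with library totals (4 and 4), with HMOX1 at 1.94, TKT at 1.38 and GPX4 at 1.56 without a corrected call. Cholesterol and fatty acid genes rose in 8 of 33 cases and fell in 9, 9 and 9 adjusted over the list alone, 11 and 8 with RLE factors, 7 and 11 with upper-quartile factors and 7 and 15 with library totals (5 and 2 with the correction), with PMVK at 1.54, FDPS at 0.92 and SREBF1 at 0.95 without a corrected call. In the unfolded protein response 9 of 20 fell and 3 rose, or 10 and 3 adjusted over the list alone (2 and 1 with the correction), with SDF2L1 at 1.65, CRELD2 at 0.88 and EDEM1 at -0.83, none called with it. Heat shock genes fell in 8 of 15 cases and rose in 4 (7 and 1). HSPA8 fell by 1.22, and HSPB1 (1.03) and HSF1 (1.18) rose without a corrected call. The integrated stress response list had 12 rises and 8 falls without HMGA2 overexpression replicate 1, 15 and 1 without replicate 3 of that group, and 13 and 1, 12 and 1 and 12 and 0 without control replicates 1, 2 and 3. Cholesterol genes had 10 and 8 with DESeq2, 8 and 8, 7 and 7 and 8 and 7 without control replicates 1, 2 and 3, and 12 and 8 without HMGA2 overexpression replicate 1. The integrated stress response counts were 12 and 4 with upper-quartile factors and 10 and 6 with library totals, and those of the unfolded protein response 3 and 15 with library totals. Corrected counts without HMGA2 overexpression replicate 2 were 13 rises and 5 falls for hypoxia, 9 and 0 for the integrated stress response and 4 and 8 for cholesterol genes.

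Polycomb and chromatin modifier genes fell in 16 of 31 cases and rose in 4, or 17 and 4 adjusted over the list alone (9 and 3 with the correction), with KDM5B at -1.34, RING1 at 1.63 and CBX2 at 1.03. Of 45 replication-dependent histone genes in the list, only 11 had enough counts to be tested. Of these 1 rose and 1 fell, 0 and 5 with library totals (1 and 2 with the correction). Synaptic and axon guidance genes fell in 7 of 24 cases and rose in 1 (2 and 4), with SEMA5A at -1.73, NTN4 at -0.64 and UNC5B at 1.17, and of these UNC5B alone was called with the correction. Histone genes had 3 rises and 1 fall with DESeq2, 1 and 0 and 2 and 0 without control replicates 1 and 3, and 2 and 3, 2 and 1 and 0 and 1 without HMGA2 overexpression replicates 1, 2 and 3. The synaptic list had 2 and 6 with DESeq2, 2 and 7 without HMGA2 overexpression replicate 1 or 3 and 3 and 6 without HMGA2 overexpression replicate 2. Its counts were 2 and 7 with RLE factors, 1 and 11 with upper-quartile factors and 1 and 13 with library totals. The corrected fit without HMGA2 overexpression replicate 2 gave 2 rises and 2 falls for histones and 3 and 5 for the synaptic list.

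No list of markers of another cell type passed camera. Of 3 haematopoietic markers tested 0 passed the edgeR test, 0 had an unadjusted p under 0.05 and 0 passed with DESeq2, and the list was too short for camera. Endothelial markers rose in 4 of 8 cases and fell in 1, 2 and 1 with upper-quartile factors or library totals (2 and 2 with the correction), VWF at 1.42, ROBO4 at 1.26 and TIE1 at -1.02. Embryonic kidney and neural markers had 3 of 9 falls and 1 rise (4 and 0), with SALL1 at -1.53, NEFH at -1.18 and SIX2 at 1.19 without a corrected call. Osteoclast markers had 1 fall among 6, 2 with upper-quartile factors and 4 with library totals (4 falls and 1 rise with the correction). Leaving out HMGA2 overexpression replicate 1 gave 1 rise among haematopoietic markers, 2 rises and 3 falls among kidney and neural markers and 2 falls among osteoclast markers, and without any 1 control 2 endothelial markers rose and 1 fell. Osteoclast markers had corrected counts of 0 and 3 without HMGA2 overexpression replicate 2.

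**Figure D4:**
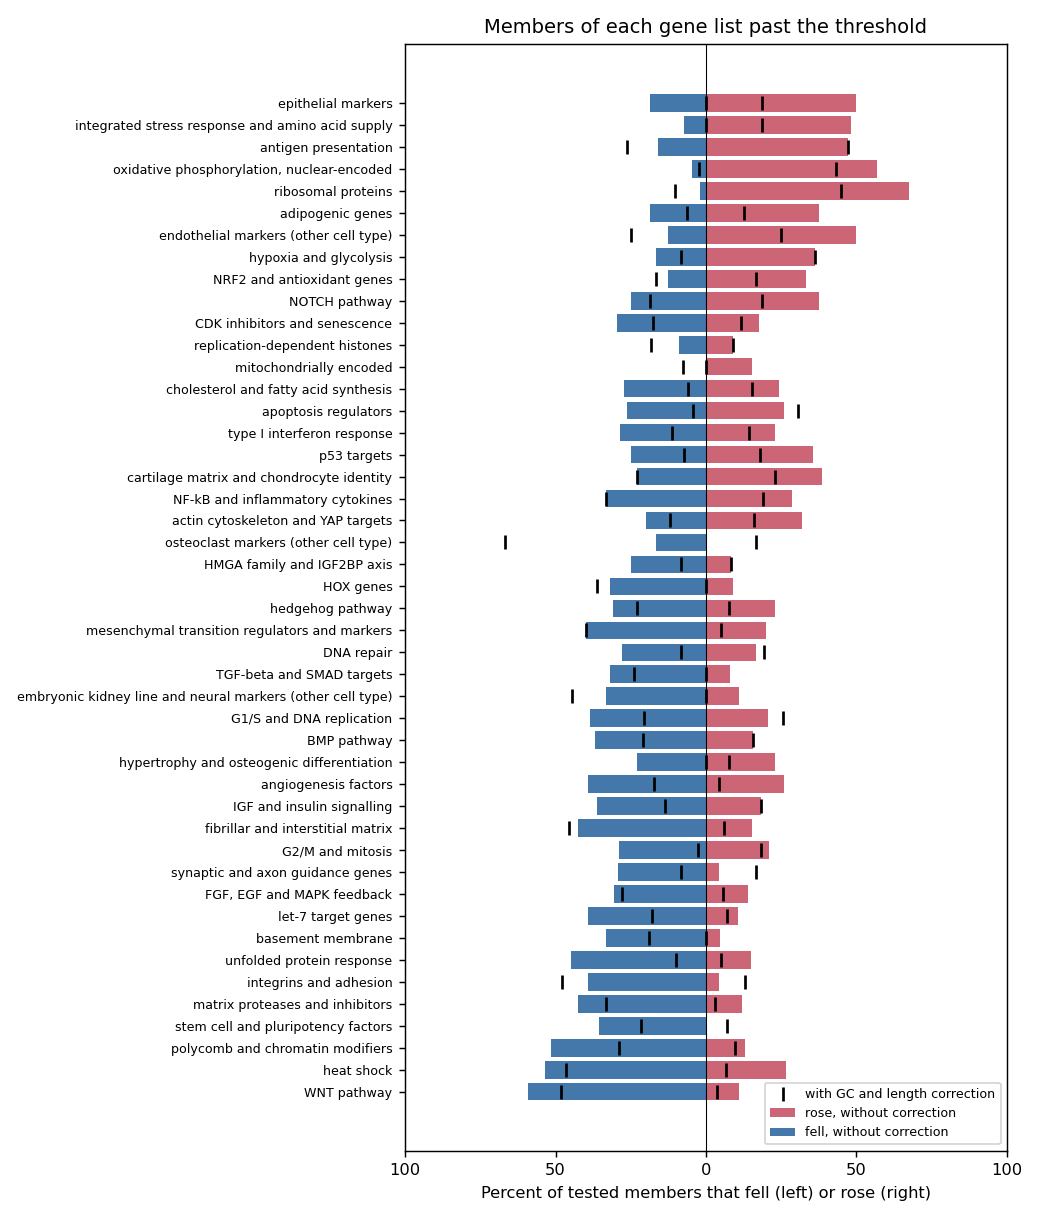
Percent of the tested members of each gene list that fell (blue, left) or rose (red, right) with HMGA2 overexpression without correction, and the same percentages with the GC and length correction (black ticks), for the 46 lists with at least 5 tested members, ordered by median log2 fold change. Ribosomal protein genes (33 of 49 rose, 22 with the correction) and WNT pathway genes (16 of 27 fell, 13 with the correction) stand near the ends, and with library totals more members fell than rose in several lists with a surplus of rises here.

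In 9 lists the median, mean and camera direction differed in sign. They were the cartilage, actin, p53, apoptosis, interferon, cholesterol and mitochondrially encoded lists, with a median below 0 and an upward mean and test, and the CDK inhibitor list, with a median of 0.02 and a downward mean and test. In the NF-kB list the median of -0.15 and the mean of -0.28 stood against an upward test (camera, adjusted p = 0.984). Ribosomal protein, histone, HLA and glycolytic genes have near-identical copies or pseudogenes, so their counts are uncertain to the extent that reads were divided between copies.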

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

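The corrections for GC content and length were chosen after the data had been seen, and the other alternatives before. HMGA2 was called under each alternative tried for it, which leaves out the fit without HMGA2 and the 1.2-fold threshold test, at 3.33 with library totals to 4.34 with the correction and without HMGA2 overexpression replicate 2, and at 3.67 to 3.89 with each library left out in turn. With a library left out, 2770 to 3483 genes rose and 2217 to 3215 fell, 2 lists rose, and 0 to 1 fell, the WNT list being lost without control replicate 2 and without HMGA2 overexpression replicate 2. Library totals gave 2155 rises and 6033 falls, as TMM moves the median of all genes. The GC and length correction gave 2149 and 1587, GC content alone 2504 and 1929, length alone 3095 and 2675, the correction with the replicate block 2102 and 1721, and the correction without HMGA2 overexpression replicate 2 2568 and 2109. Each of these fits removes the trend it models by construction. Calls reversed against the uncorrected fit numbered 55, 53, 4, 54 and 110 in that order. For gene lists, an estimated correlation gave 0 up and 0 down, with and without the correction. Fry, which does not compare a list with other genes, gave 7 up and 16 down, the stricter filter 0 down, and the correction 8 down; the cause was not tested for the filter.

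Samples with the same number did not deviate together, the correlations of their deviations from the group means being 0.09, -0.07 and -0.12, and control replicates 2 and 3 correlated best with libraries of another number, so the numbers were not taken as pairs. With the replicate number as a block 3187 genes rose and 3305 fell, and all 153 other named values (genes and lists) kept their call.

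No named gene changed direction under an alternative fixed in advance. RPL22 lost its call with RLE factors, DESeq2 and without each control in turn, FZD2, WNT10B, HEY2 and HOXD4 with library totals, WNT10B without control replicate 1, HEY2 and HOXD4 without control replicate 2, and IRS1 without control replicates 2 and 3 and HMGA2 overexpression replicate 1. Reversed values, in log2, came from the corrections. With GC and length they were -0.11 for HMGA1, -0.071 for PHOSPHO1, -0.54 for FZD2, -0.037 for HES4, -0.29 for IGFBP6, -0.13 for CRELD2, -0.049 for CEBPB and -0.41 for HSPB1. With the block added, the same genes in this order had -0.12, -0.071, -0.54, -0.021, -0.30, -0.12, -0.063 and -0.44. Without HMGA2 overexpression replicate 2 they had -0.15, -0.18, -0.56, -0.029, -0.25, -0.079, -0.20 and -0.61, and JUNB had -0.032, LIN28A 0.025 and HOXD4 -0.055. With GC content alone, HMGA1 had -0.022, PHOSPHO1 -0.012, FZD2 -0.47 and SREBF1 -0.054. Of these, FZD2 passed the threshold in every such fit and HSPB1 with the block or without HMGA2 overexpression replicate 2. Depth limits genes near the floor of 3 counts. In the simulation without a trend 16.5% of 1.5-fold changes were recovered, and the part of depth in this was not tested.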

Other observations

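The gene lists and genes of the first paragraph, and the test on mitochondrially encoded genes, were chosen after the result was seen; the other tests were written down before. With the GC and length correction, camera also called 7 lists downward that had not passed without it. HOX genes fell in 8 of 22 cases with 0 rises (adjusted p = 0.00434), matrix proteases and inhibitors in 11 of 33 with 1 rise (adjusted p = 0.000886), fibrillar matrix genes in 15 of 33 with 2 rises (adjusted p = 0.0193), mesenchymal transition genes in 8 of 20 with 1 rise (adjusted p = 0.0240), TGF-beta genes in 6 of 25, heat shock genes in 7 of 15 with 1 rise, and histone genes in 2 of 11 with 1 rise (adjusted p = 0.0257 for each of these 3). Only 11 of the 45 listed histone genes had enough counts to be tested, so that call does not describe histone genes at large. Without HMGA2 overexpression replicate 2 there were 5 falls and 0 rises for HOX genes, 10 and 1 for TGF-beta genes and 2 and 2 for histone genes. With an estimated correlation none of the 10 called lists passed (camera, adjusted p = 0.455 or more). Among genes high in both fits, A2M, the protease inhibitor alpha-2-macroglobulin, rose by 2.16 and by 2.75 with the correction, and SELENOP, a selenium transport protein, by 2.06 and 2.22. IGFBPL1 stood at -1.57 and at -2.85 with the correction, the small proteoglycan gene BGN at -1.17 and -1.97, and the receptor phosphatase gene PTPRS at -1.35 and -1.94, all past the threshold in both. TMED3 rose by 1.49 and 2.24, but its corrected value rests on a longest annotated transcript of 16555 nucleotides, whose use in these cells was not tested. The longest transcript was taken for every gene, so all corrected values and counts carry this limit.

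The first pattern is that fold changes follow transcript GC content and length. A difference in depth is argued against by HMGA2 overexpression replicate 3, which had more counts (18238226) than any control. Its log2 gap between the highest and lowest decile of GC content was 0.76, like its group and unlike the controls, though this rests on 1 library. Thinning every library to 14079227 counts left Spearman's rho with GC content at 0.563 and 3225 rises and 3116 falls. Thinning keeps each gene's expected share of its library, so it could hardly have removed the trend. Transcription of nuclear genes by base composition as the whole cause predicts no relation of the 13 mitochondrially encoded genes to values predicted from nuclear genes. Their fold changes did follow those values (rho = 0.571, permutation p = 0.0441, adjusted p = 0.0441 over 4 lists), which speaks against it only weakly. The test was chosen after the result was seen, passed narrowly, and permutes the 13 genes as if they were independent. A GC and length bias of the reads remains a candidate explanation. Fold changes within the 49 ribosomal protein genes followed the prediction from all other genes (rho = 0.347, permutation p = 0.0149, adjusted p = 0.0198). So did oxidative phosphorylation (rho = 0.699, permutation p = 1e-05, the smallest that permutations can give, adjusted p = 4e-05) and interferon genes (rho = 0.647, permutation p = 8e-05, adjusted p = 0.00016). The trend runs across all genes, so a response of the cells that differs by transcript composition predicts the same. These 3 results therefore do not favour a bias of the reads over such a response. A response of the cells to HMGA2 that differs by transcript composition stays open too, because the main gap lies between the groups and the labels give no batch. The log2 gap between the highest and lowest decile of GC content was -0.63 to -0.96 in controls and 0.71 to 0.76 in HMGA2 overexpression libraries. These gaps are relative to the mean of all 6 libraries, so any difference between the groups gives opposite signs. Control libraries also differed among themselves, without the construct. Relative to the own group mean, rho with GC content was 0.22, -0.32 and 0.08 in control replicates 1, 2 and 3. It was -0.03, 0.04 and -0.02 in HMGA2 overexpression replicates 1, 2 and 3.

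The second pattern is HMGA2 overexpression replicate 2, which lies nearer the controls. Genes called without it at 2-fold or more stood in it at a median of 0.603 of the way from control to the other libraries for rises (1774 genes) and 0.747 for falls (793 genes), and HMGA2 itself at 0.799. A GC and length trend of that library is argued against, as its share on the first principal component was 0.782 before and 0.695 after the correction. Admixture of control-like cells or RNA predicts equal shares for rises and falls, and these differed by -0.144, between the bounds set beforehand. Shares also differed in HMGA2 overexpression replicate 3 (1.38 for rises and 0.984 for falls, against 0.987 and 1.02 in replicate 1). Each share is relative to the other libraries of the group, so the references for replicates 1 and 3 both contain replicate 2. Whether such a gap is specific to replicate 2 therefore cannot be told. Admixture cannot be told apart from a weaker response at the lower HMGA2 level.

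The third pattern would be copy number differences between cultures, which could shift whole chromosomes. The tables argue against this once the GC and length trend is removed, because the corrected median furthest from 0 was -0.0953 on chromosome 21 and no chromosome passed camera (lowest adjusted p = 0.850 over 23 chromosomes). Uncorrected medians ran from -0.41 on chromosome 13 to 0.57 on chromosome 19, and whether they hold any part beyond base composition rests on that correction. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many rises (3281) or falls (3196). The highest other count was 0 for each with the edgeR test and with DESeq2 (64 rises and 123 falls at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Every other split also puts control and HMGA2 overexpression libraries on the same side, so the gap between the groups adds to its spread. Counts near 0 were to be had there in advance, and no conclusion is drawn from them.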
